A study of Mus musculus with 4 samples.

How the data were processed

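The series profiled E14Tg2a mouse embryonic stem cells. Per the labels' protocols, the cells (passages 20 to 35) were fixed with 1% formaldehyde for 10 min, chromatin was sheared to about 200 to 500 bp, and each immunoprecipitation used 2 µg of antibody. NF-YA was precipitated with a mouse monoclonal antibody and NF-YB and NF-YC with rabbit polyclonal antibodies, per the labels. The 4 samples comprise 1 library each for NF-YA, NF-YB, NF-YC and input DNA. The input entered only as the background that the authors gave their peak caller, and its own reads were not analysed here. The knockdown expression arrays that the series' design text mentions were not analysed here.

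Reads were mapped to mm9 with Bowtie, per the submitters' processing notes. The aligner's version and settings are not given in the sources used here. Binding sites were called by the authors with SISSRs 1.4 separately for each library, per the file headers, against 1 background file of 13767116 tags. The e-value was 10, the p-value threshold 0.001, the scanning window 20 bp and the mappable fraction of the genome 0.80, per the file headers. A single tag was kept per genomic position, at least 2 directional tags were required on each side, and sites supported by tags of a single strand were not reported, per the file headers. Keeping 1 tag per position removes amplification duplicates and also caps the tag count of very strong sites. A site needed at least 14 tags for NF-YA and NF-YC, 15 tags for NF-YB and a fold of at least 7.00, per the file headers.

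Each deposited list gives a site's chromosome, start and end, its tag count, its fold enrichment and its p-value. The deposited tag counts are whole numbers of tags assigned to a site in that library, not normalized. The stretch over which the site tags and input tags were counted is not given in the sources used here. It was wider than the printed interval at the strongest sites, since a 40 bp interval with 1 tag kept per position cannot hold the 312 tags of the first NF-YA site. The deposited fold is the ratio of those tags to background. For 92.5% of NF-YA, 96.7% of NF-YB and 94.9% of NF-YC sites it equalled, within rounding of 0.005, the tag count divided by a whole number of input tags scaled by the ratio of kept tags to background tags (0.834, 1.01 and 0.827). These whole input counts ranged from 1 to 15. The recovery took 1 as the lowest possible count, so 0 could not be found. A site with a value of 1 may have held no input tag, and its fold may then reflect a floor. The sites where the fold did not equal such a quotient were wider than 60 bp in each case (348 NF-YA, 92 NF-YB and 137 NF-YC sites). The deposited p-value reached at most 0.00087 and was used only to describe the lists. Tag counts and folds are the authors' values and were ranked only within their own list, apart from comparisons of tags scaled to the kept tags of each library.

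A site's centre was the midpoint of its start and end, as deposited; whether positions count from 0 or 1 is not given in the sources used here. Sites of 2 lists were called shared when their centres lay within 200 bp, the low end of the fragment lengths in the labels. Regions were formed by chaining sites of the 3 lists whose neighbouring centres lay within 200 bp, and 16 of the regions held more than 1 site of a list. Shares carry exact (Clopper-Pearson) 95% binomial intervals over sites, which cover counting error only. Sharing was compared with 1000 circular shifts of a list along each chromosome between the first and last site of any list, since chromosome lengths of the build were not used here. For regions of all 3 subunits, the NF-YB and NF-YC lists were shifted independently. The shifts test whether these lists coincide, not whether conditions differ. No p-value is given across sites, and the shares of tag-matched draws given later describe these sites only. Clustering was compared with 1000 random placements. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

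The functions were tested on simulated lists of the real lengths. Of 2774 simulated NF-YB sites, 2000 were planted at NF-YA sites and 2001 were found shared, and 1500 of 1500 planted regions of all 3 subunits were recovered. None of 40 unrelated simulated lists exceeded all of 100 shifts. The unrelated sites were placed uniformly along each chromosome, and the planted partners lay well inside the 200 bp limit. The simulations thus check the code, and unrelated lists clustered like the real ones were not simulated.

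The sharing distance, the region rule, the shifts and random placements, the ranking of tag counts within a list, the alternatives listed below and the rule for named sites were fixed before the data were examined. The division of each list into 10 groups by tag count, the correlation of tag counts between subunits, the input counts recovered from the fold and the windows of 100 kb with their minimum of 7 regions were added after the data had been seen. The rule names the 5 sites with most tags in each list and the 10 regions of all 3 subunits with the best mean within-list tag rank. Alternatives were other sharing distances (interval overlap of 1 bp, 100, 500 and 1000 bp), subsets of strong sites, lists of equal length, other chance models, ranking by fold, and another neighbour distance. The share of sites at promoters, the share with a CCAAT box, and gene lists at bound promoters had also been planned. They were not run, because the gene table used here is of GRCm38 and the sites are in mm9, so no gene was assigned to any site. As the table holds no mm9 positions, exons, introns and untranslated regions are not given for any site.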

Results

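NF-Y is a transcription factor built of the subunits NF-YA, NF-YB and NF-YC. NF-YA makes the sequence-specific contact with the CCAAT box, and NF-YB and NF-YC carry histone-fold domains and dimerize with each other. Each subunit was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14Tg2a cells, a mouse embryonic stem cell line of 129/Ola origin, with 1 library per subunit and 1 input DNA library. The maps address where in the genome each subunit was bound and how far the maps coincide. The NF-YA library held 15698185 tags, of which 11479998 (73.1%) were kept for site calling. The NF-YB library held 18821206 tags with 13859303 kept (73.6%), and the NF-YC library 16335995 tags with 11390494 kept (69.7%). The input library used as background held 13767116 tags. No subunit had a replicate library, so the comparisons below describe these libraries and have no replicate check.

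The NF-YA list was the longest, with 4642 sites, against 2774 sites for NF-YB and 2675 for NF-YC. NF-YA sites thus outnumbered NF-YB sites 1.67-fold and NF-YC sites 1.74-fold, although the NF-YB library was the most deeply sequenced of the 3. Sites were short: the median width was 60 bp for NF-YA, 40 bp for NF-YB and 60 bp for NF-YC. The median NF-YA site was supported by 34 tags (range 14 to 312), the median NF-YB site by 43 tags (15 to 351) and the median NF-YC site by 36 tags (14 to 267). Median fold enrichment over input, as the authors' caller gave it for each site, was 16.8 for NF-YA, 16.9 for NF-YB and 16.5 for NF-YC. The tag counts of all sites summed to 2.09% of the kept tags for NF-YA, 1.18% for NF-YB and 1.07% for NF-YC. These sums move with how much was called in each library, and the tags of a site are not confined to its printed interval.

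Most NF-YB and NF-YC sites lay at NF-YA sites. Of the 2774 NF-YB sites, 2329 (84.0%, exact 95% binomial interval 82.5 to 85.3) had an NF-YA site with its centre within 200 bp. Of the 2675 NF-YC sites, 2338 (87.4%, 86.1 to 88.6) had one. NF-YB and NF-YC coincided at 1778 of the 2675 NF-YC sites (66.5%, 64.6 to 68.3). The NF-YA list was matched less completely in return: 50.2% of its sites (48.7 to 51.6) had an NF-YB site and 50.5% (49.0 to 51.9) an NF-YC site. When one list was shifted along its chromosomes 1000 times, the mean sharing was 0.0843% for NF-YA with NF-YB, 0.0848% for NF-YA with NF-YC and 0.0497% for NF-YB with NF-YC. The highest of the shifted values were 0.288%, 0.748% and 0.262%, so each observed share lay above every shifted one. The shifts did not keep sites at promoters or other sequence that many factors may favour. Every list was also called against the same input library, a link that shifting breaks. The excess over the shifts thus shows that the lists coincide, and does not show that this is specific to NF-Y. The binomial intervals of the shares cover counting error over sites only.

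The gap between the pairs narrowed when the lists were made equally long. With the 2675 sites of most tags taken from every list, 68.1% of NF-YB sites had an NF-YA site (66.3 to 69.9), 71.0% of NF-YC sites had an NF-YA site (69.3 to 72.7) and 65.5% of NF-YC sites had an NF-YB site (63.7 to 67.3). NF-YC was matched more often by NF-YA than by NF-YB in this setting. Both shares are taken over the same NF-YC sites, so their separate intervals do not test the difference. The intervals for NF-YA with NF-YB and for NF-YB with NF-YC overlapped, and no difference between pairs was tested. Equal length cut the NF-YA list at 30 tags, against 15 for NF-YB and 14 for NF-YC, so NF-YA partners of fewer tags were left out.

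Joined across the lists, the sites formed 5350 regions, and 1724 of these (32.2%, 31.0 to 33.5) held all 3 subunits. Regions with NF-YA and NF-YB numbered 601, those with NF-YA and NF-YC 613, and those with NF-YB and NF-YC but no NF-YA site 56. NF-YA was therefore present at 1724 of the 1780 regions that held both NF-YB and NF-YC (96.9%, 95.9 to 97.6). Regions of a single list were mostly from NF-YA (1693), with 385 from NF-YB and 278 from NF-YC. No region of all 3 subunits arose in any of 1000 sets in which the NF-YB and NF-YC lists were shifted independently. These shifts have the same limits as those of the pairs of lists. The regions of NF-YB and NF-YC without NF-YA had a mean of 1.42 in the shifted sets, 39.5 times fewer than the 56 observed. In 1 of the 1000 sets they reached 60: there the NF-YB and NF-YC lists were shifted on chromosome 15 to within 157 bp of their real alignment. The next highest set had 8. The order of the single-list regions depended on list length: with 2675 sites from every list, 466 regions were of NF-YA alone, 610 of NF-YB alone and 534 of NF-YC alone. In that setting the 3-subunit regions numbered 1517 of 4049, and the regions of NF-YB and NF-YC without NF-YA rose to 238. It cut the NF-YA list at 30 tags, but NF-YB at 15 and NF-YC at 14. NF-YA sites of fewer tags were left out, so NF-YB or NF-YC sites beside them then counted as without NF-YA. The changed order thus does not compare the subunits at a like minimum of tags.

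**Figure D1:**
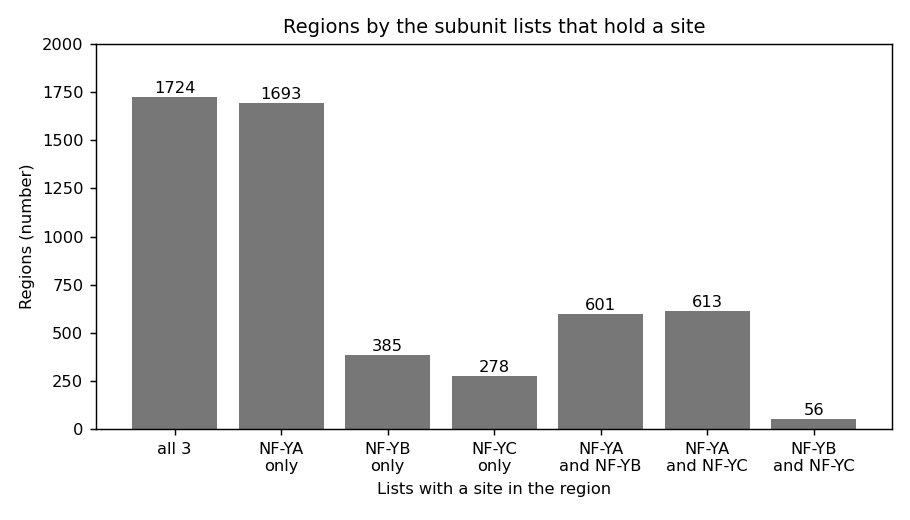
Number of regions (vertical axis) by which subunit lists had a site in them (horizontal axis), for all 5350 regions. Regions of all 3 subunits (1724) and of NF-YA alone (1693) were the most numerous, but with lists of equal length NF-YA alone fell to 466, below NF-YB alone (610) and NF-YC alone (534). Equal length cut the NF-YA list at 30 tags, NF-YB at 15 and NF-YC at 14, so that order is not at a like minimum.

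Sites found with every subunit tended to have more tags than the other sites of their list. NF-YA sites shared with both other lists had a median of 70 tags, against 33 for those shared with a single other list and 21 for those in neither. The corresponding medians were 58, 33 and 21 tags for NF-YB and 44, 28 and 20 tags for NF-YC. In percentiles of tag count within their own list, the sites shared with both others had medians of 77.5 for NF-YA, 64.1 for NF-YB and 60.3 for NF-YC, while unshared sites had medians of 25.3, 17.4 and 18.8. The contrast was smaller in percentiles of fold, where shared sites had medians of 76.6, 61.7 and 58.8 and unshared sites 28.1, 38.2 and 32.7. It was also smaller when sharing required overlapping intervals, with unshared medians of 27.6, 26.9 and 32.9 by tag count. By tag count, the first quartiles of the sites shared with both others within 200 bp were 58.8 for NF-YA, 39.7 for NF-YB and 36.6 for NF-YC, so many of them lay low in the NF-YB and NF-YC lists. In the tenth of the NF-YA list with most tags, 428 of 460 sites (93.0%, 90.3 to 95.2) were shared with both others and 3 with neither. In the tenth with fewest tags, 6 of 399 were shared with both (95% interval 0.554% to 3.24%) and 326 (81.7%, 77.6 to 85.4) with neither. For NF-YB the share with both others went from 24.0% among the sites of fewest tags to 97.1% among those of most tags, and for NF-YC from 28.7% to 88.9%. The NF-YA list was longer above a similar minimum of 14 or 15 tags. Its 2675 strongest sites ended at 30 tags, and 25.1% of NF-YA sites with 29 to 34 tags were shared with both. The low ends of the 3 lists by rank are thus not comparable. Across the 1724 regions of all 3 subunits, tag counts were correlated between NF-YA and NF-YC (Spearman's rho 0.76), NF-YA and NF-YB (0.66) and NF-YB and NF-YC (0.59). These correlations run across regions, which are not independent replicates. Every list stops at 14 or 15 tags. With correlated tag counts, a site weak in its own list would often miss the minimum in another. Sharing could thus rise with tag count even if every subunit were at every site.

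**Figure D2:**
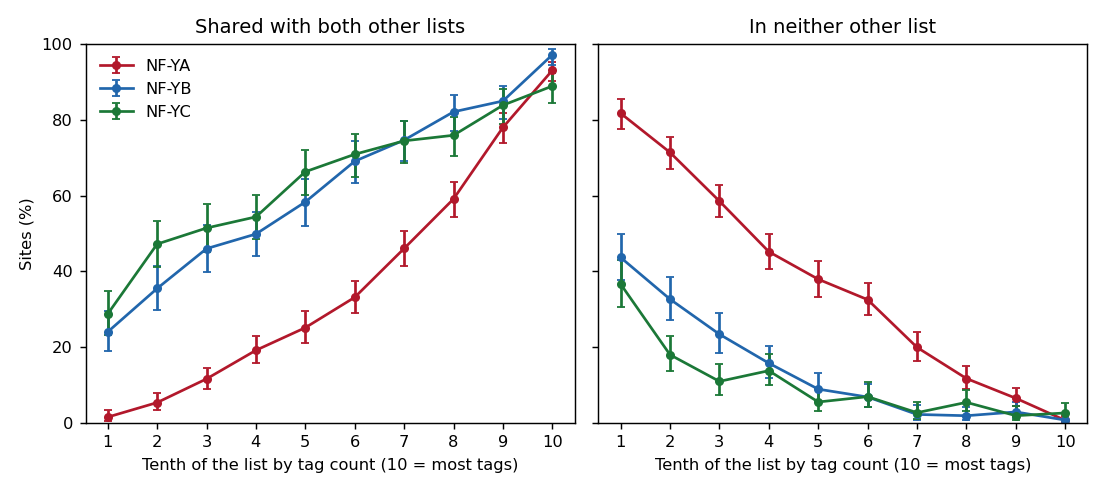
Percent of sites shared with both other lists (left) or in neither (right) in 10 groups of the subunit's own list ordered by tag count, with exact 95% binomial intervals as bars. Sharing with both others reached 93.0% for NF-YA, 97.1% for NF-YB and 88.9% for NF-YC in the tenth with most tags. Every list stops at 14 or 15 tags, which alone could lower sharing at weak sites.

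Where the subunits coincided, their centres lay close together. The median distance between nearest centres was 20 bp for NF-YA and NF-YB over 2330 pairs (quartiles 10 and 40 bp), 20 bp for NF-YA and NF-YC over 2343 pairs (10 and 50 bp) and 30 bp for NF-YB and NF-YC over 1783 pairs (10 and 50 bp). Between 79.1% and 82.9% of the pairs lay within 50 bp and 96.0% within 100 bp. The caller's scanning window was 20 bp, which limits this resolution. Within a list, no 2 centres lay closer than 240 bp, slightly above the fragment lengths the caller estimated (234 bp for NF-YA, 224 bp for NF-YB and 238 bp for NF-YC), so neighbouring sites inside a fragment length were not separated.

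**Figure D3:**
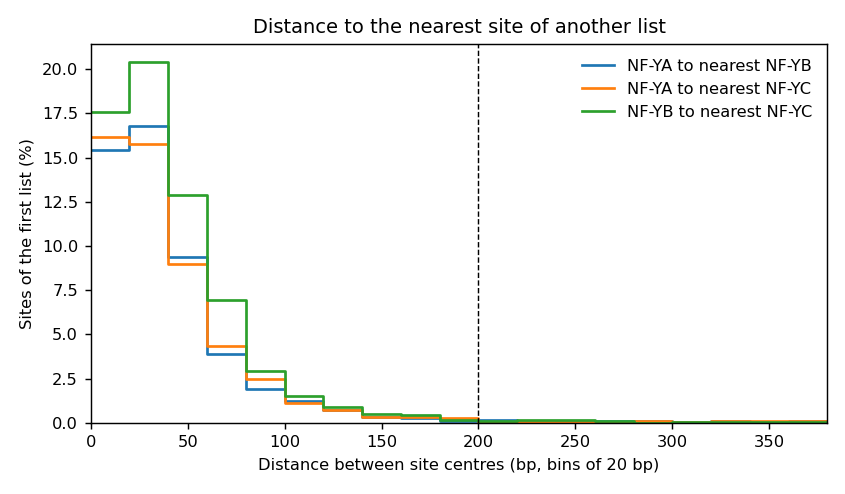
Percent of the first list's sites (vertical axis) whose nearest site of the second list lay at a given distance between centres (horizontal axis, bp), for the 3 pairs of lists, with the 200 bp limit for sharing dashed. The counts fell steeply, with 96.0% of the pairs under the limit lying within 100 bp.

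The 5 sites with most tags in every list lay in regions of all 3 subunits. The NF-YA site with most tags lay on chromosome 15 from 102236451 to 102236491 (mm9), with 312 tags, and its region held 282 NF-YB tags and 176 NF-YC tags. The next NF-YA sites were on chromosome 8 at 72520351 to 72520391 (311 tags), chromosome 10 at 128133491 to 128133531 (307 tags), chromosome 11 at 96839151 to 96839191 (293 tags) and chromosome 11 at 55282971 to 55283031 (292 tags). The NF-YB list was led by chromosome 11 at 119960091 to 119960131 (351 tags), chromosome 15 at 76181611 to 76181671 (308 tags), chromosome 7 at 75894311 to 75894351 (305 tags), chromosome 2 at 158593711 to 158593751 (304 tags) and chromosome 8 at 23916231 to 23916271 (303 tags). These ranked 29, 6, 38, 157 and 119 in the NF-YA list and 4, 36, 4, 284 and 121 in the NF-YC list. The NF-YC list was led by a site on chromosome 3 at 90279771 to 90280031 with 267 tags, which ranked only 305 in the NF-YA list and 564 in the NF-YB list. It was also the widest of the leading sites, at 260 bp. The next NF-YC sites were chromosome 18 at 36720011 to 36720051 (207 tags), chromosome 10 at 127520171 to 127520211 (191 tags), chromosome 11 at 119960071 to 119960111 (189 tags) and chromosome 7 at 75894291 to 75894331 (189 tags).

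Ranked by the mean of the 3 within-list ranks, the region on chromosome 15 at 102236411 to 102236491 stood first, with ranks 1 for NF-YA, 7 for NF-YB and 13 for NF-YC. It was followed by chromosome 15 at 78893451 to 78893551 (ranks 13, 12 and 6), chromosome 11 at 119960071 to 119960131 (29, 1 and 4), chromosome 15 at 76181611 to 76181671 (6, 2 and 36) and chromosome 7 at 75894251 to 75894351 (38, 3 and 4). The remaining regions of the first 10 were chromosome 12 at 72116751 to 72116871, chromosome 14 at 52723791 to 52723911, chromosome 15 at 80541571 to 80541631, chromosome 11 at 55282971 to 55283051 and chromosome 7 at 117205011 to 117205151. Chromosome 15 thus carried 4 of the 10. The region at 76181611 had the highest fold enrichment of the 10 in each list, 348 for NF-YA, 306 for NF-YB and 175 for NF-YC. Its recovered input level was 1 tag in each list, the lowest that the recovery allowed.

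Sites were spread unevenly over the chromosomes, in much the same way for the 3 subunits. Chromosome 11 was the densest, with 3.47 NF-YA, 2.06 NF-YB and 1.99 NF-YC sites per Mb between the first and last site of any list. Chromosome 19 followed for NF-YA with 2.95 sites per Mb, chromosome 17 with 2.83 and chromosome 7 with 2.75, against 1.83 over the genome as a whole. The X chromosome was the sparsest for every subunit, with 0.728 NF-YA, 0.364 NF-YB and 0.370 NF-YC sites per Mb. These densities were not adjusted for chromosome copy number or gene content, so they do not show weaker binding per copy. The share of regions with all 3 subunits was 33.6% on chromosome 11 (29.3 to 38.1) while 32 of 128 regions had all 3 on the X chromosome (17.8% to 33.4%), with overlapping intervals. Chromosome Y carried 2 NF-YA, 3 NF-YB and 3 NF-YC sites.

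**Figure D4:**
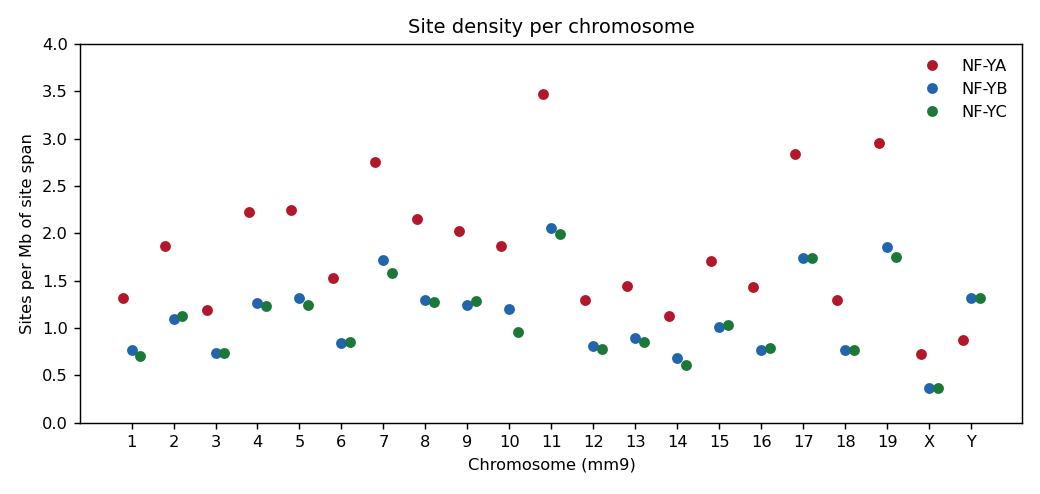
Sites per Mb (vertical axis) for each mm9 chromosome (horizontal axis) and subunit, over the span between the first and last site of any list. Chromosome 11 was highest for the 3 subunits (3.47, 2.06 and 1.99 sites per Mb for NF-YA, NF-YB and NF-YC), and the X chromosome lowest.

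Regions also clustered at short range. Of the 5350 regions, 952 (17.8%) had another region within 10 kb, 3.86 times the mean of 247 over 1000 sets of regions placed at random on the same chromosomes (highest set 319). When each region was instead moved by up to 100 kb from its own place, the mean was 735 and the highest 845, still below the observed count. The observed count was only 1.30 times that mean, so much of the excess over random placement remained after these local moves. Neighbouring centres lay within 500 bp of each other in 87 cases and within 1000 bp in 154 cases.

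Windows of 100 kb with 7 or more regions numbered 5 of the 3856 windows that held a region, and the fullest window in each of 1000 random placements held between 3 and 6. These placements were uniform along each chromosome, so they did not keep its denser parts. Local moves of regions were not applied to the windows. The fullest lay on chromosome 13 from 23600001 to 23700000 (mm9), with 12 regions, 5 of them with all 3 subunits. Chromosome 13 also held the next windows, at 23800001 to 23900000 (10 regions, 5 with all 3) and at 21800001 to 21900000 (8 regions, 4 with all 3). The others lay on chromosome 11 at 58700001 to 58800000 and on chromosome 8 at 74000001 to 74100000, each with 7 regions, 3 of them with all 3 subunits. The windows on chromosome 13 held 26 NF-YA, 20 NF-YB and 23 NF-YC sites, with median tag count percentiles of 66.6, 64.4 and 65.9 in their own lists.

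**Figure D5:**
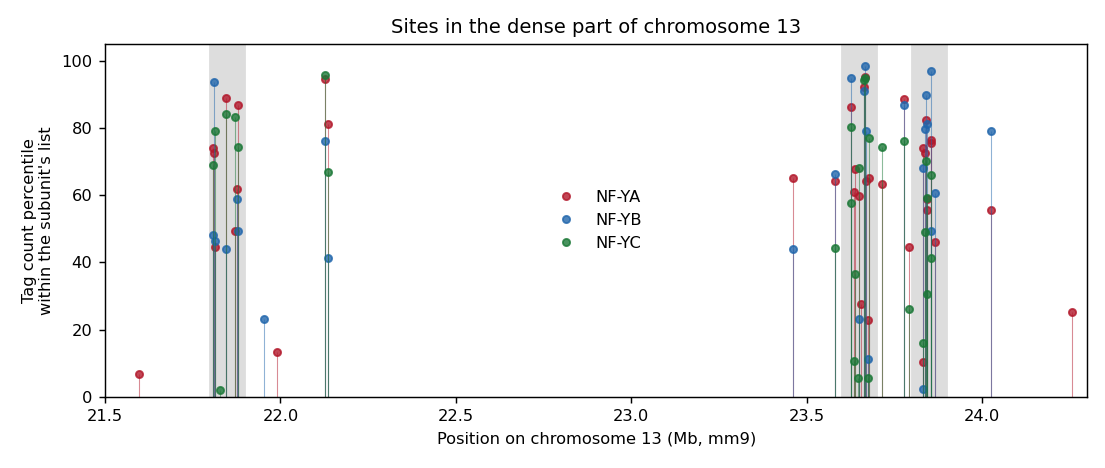
Tag count percentile within the subunit's own list (vertical axis) of each NF-YA, NF-YB and NF-YC site against position on chromosome 13 (horizontal axis, Mb, mm9), with the 3 windows of 7 or more regions shaded. The shaded windows held 12, 10 and 8 regions.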

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

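The 3 pairwise shares lay above every random set in all 12 settings, including 2 chosen after seeing the data (sites wider than 200 bp left out, chromosome Y left out). NF-YA with NF-YB ranged from 67.9% to 87.7%, NF-YA with NF-YC from 71.0% to 88.1% and NF-YB with NF-YC from 51.7% to 67.7%. The highest random value in any setting was 5.50%, for NF-YA with NF-YC at 1000 bp, where the random mean was 0.404%. No random set kept sites at promoters or other favoured sequence. Passing every set thus shows that the lists coincide, and not that this is specific to NF-Y. The lowest shares came from requiring the site intervals to overlap, except for NF-YA with NF-YC, where lists of equal length gave the lowest. The 1724 regions of all 3 subunits became 843 with the upper part of each list by tag count and 722 with the upper part by fold, since these settings keep about 50% of the sites. They stayed between 1406 and 1723 in the other settings that change the sites or the distance. Ranking by fold moved the median percentile of NF-YB sites shared with both other lists from 64.1 to 61.7. The unshared medians rose by fold, from 17.4 to 38.2 for NF-YB and from 18.8 to 32.7 for NF-YC, and with interval overlap to 26.9 and 32.9. Counting neighbours within 50 kb instead of 10 kb raised the clustered regions from 952 to 2564, against a random mean of 1114 and a random maximum of 1253. The other 48 of the 52 alternative values kept their direction, with region counts within 1.5 times the reported ones. Settings that changed only the chance model left the observed values as they were, so those values could not move. Leaving out chromosome Y removed few sites, and the pairwise shares were held to no bound on size. The tally therefore overstates how far the values were tested. The settings intended for promoter share, CCAAT share and gene lists were not run for want of mm9 annotation. No paired analysis was possible because each subunit had 1 library, and for the same reason no replicate could be left out. Depth limits the lists at 14 or 15 tags: a site below that in a library is missing from its list, which does not show that the subunit was absent.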

Other observations

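All tests of explanations in this part, and the bounds that decide them, were chosen after the result was seen. The bounds for local input at NF-YB and NF-YC sites and for copied sequence on chromosome 13 were also changed once the first values were known: by the first bounds those explanations counted as argued against, and by the bounds used here they stay open.

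The dense windows on chromosome 13 have a candidate explanation in clusters of replication-dependent histone genes: the GRCm38 gene table lists 53 protein-coding histone genes on that chromosome, and 53 of these neighbour another one. The builds differ, so no position was compared and this stays open. A technical explanation is that reads from near-identical gene copies piled up there, which would raise the input as well. Median input tags per site were 2.5 in the windows against 3 in the whole list for NF-YA, 3 against 2 for NF-YB and 2 against 3 for NF-YC. These small values go both ways and leave that explanation open too.

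The NF-YA list was longer than the others by 1.67-fold and 1.74-fold. Greater depth is argued against: the NF-YA library had 0.828 times the kept tags of the NF-YB library and 1.01 times those of the NF-YC library. Weaker enrichment in the NF-YB and NF-YC libraries, with a minimum of 14 or 15 tags for calling a site, may contribute to the difference. Only 0.652% of the tenth of NF-YA sites with most tags (3 of 460) were in neither other list. The same would be seen if NF-YA bound alone at its weaker sites, so this value does not separate the 2 explanations. At the regions of all 3 subunits the median was 6.10 tags per 1000000 kept tags for NF-YA, 4.18 for NF-YB and 3.86 for NF-YC. Those regions were chosen by passing in every library, and the 3 antibodies differ, so antibody efficiency and occupancy cannot be separated here. Binding of NF-YA without the other subunits stays open for its weaker sites: 58.5% of the lower-ranked part of the list (percentile 50 or below) were in neither other list, and the lists hold no NF-YB or NF-YC tags below the minimum.

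Some strong sites were in 1 list only. Among the 20% of sites with most tags, 33 NF-YA, 10 NF-YB and 12 NF-YC sites were in neither other list. A partner site just beyond the 200 bp limit is argued against for most, since 9.09% of the 55 had one within 500 bp. High local input may contribute for NF-YA: the unshared sites had a median of 6 input tags, and 0.06% of 10000 draws of shared sites matched on tag count were as high. For NF-YB and NF-YC the median was 5.5 input tags, matched by 6.76% and 11.8% of draws, and the few sites leave it open; no biological explanation was tested.

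In the tenth of each list with most tags, 7 of the 12 unshared sites came from NF-YC, among them chromosome 13 at 109106471 to 109106511 (118 tags) and chromosome 11 at 96147871 to 96147911 (117 tags). The 2 unshared NF-YB sites among them had a site of another list at 230 and 210 bp. The 3 NF-YA sites had none nearer than 38500 bp, the strongest being chromosome 5 at 119505731 to 119505771 (141 tags).

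The fold values carry information on the input library at the bound sites. The recovered input level was 1, the lowest that the recovery allowed, at 964 NF-YA, 673 NF-YB and 517 NF-YC sites. Whether these sites held 1 input tag or none is not known. At 1532 regions of all 3 subunits where the input count was recovered in each list, the 3 counts were equal in 49.4% and within 1 tag in 82.9%. The highest input count, 15 tags in each list, was at chromosome 11 from 85166611 to 85166651, where NF-YA had 198 tags and NF-YB 173. Several sites on chromosome Y were wide: the NF-YC sites at 1790651 to 1792071 and at 2786951 to 2788211 measured 1420 and 1260 bp, against a median of 60 bp in that list.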
